A study of Mus musculus with 16 samples.

How the data were processed

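RNA was sequenced from 16 libraries of sorted mouse colon epithelial cells. Per the labels' protocols, the mice were 6–8 weeks old, cells were released from the distal colon with EDTA and collagenase, and gates for mCherry were set against a C57Bl6 mouse without the reporter. Goblet cell lysates were purified on MinElute columns and the other epithelial cells on Mini columns, so the purification differed between the sorted fractions in the same way as the cell type. Libraries were made with the TruSeq Stranded Total RNA kit with Ribo-Zero Gold (revision E) and sequenced from both ends, per the labels' protocols.

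The deposited values were whole-number read counts per gene symbol, 1 column per library. The submitters' processing notes name FastQC 0.11.2, STAR 2.4.0f, HTSeq 0.6.1p1, DESeq2 1.14 and the mouse build mm10, without the role or order of each. The annotation, the strand setting of the counting and any filter are not given in the sources used here. A second deposited table held a normalized signal, the counts divided by 1 size factor per library (0.674–1.26). It was used only to check that this ratio is constant within each library, and no test was run on it.

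The gene counts summed to 10085637–17111987 per library over 21442 genes. The 3 entries that name no gene held 47.1–54.7% of all counts and stayed out of library sizes and tests. As shares of all counts, reads without a feature made up 20.1–28.2%, reads aligned to several places 21.9–26.7% and ambiguous reads 0.466–0.568%. Between 15108 and 18056 genes were detected per library, and the 20 most abundant genes held 9.41–13.2% of gene counts. By group, detected genes ran over 17221–18056 in SpdefKO_GC, 16553–17105 in WT_GC, 15108–15775 in SpdefKO_EC and 15648–15921 in WT_EC. The ranges of SpdefKO_GC and WT_GC did not overlap, although their mean gene counts per library were alike (14.4 and 14.5 M). Correlations between libraries of a group were 0.983–0.994 across genes, which are not independent replicates. No pair of libraries within a group differed as little as sampling noise (chi-square per degree of freedom 4.53–34.5), so none of these was counted as a duplicate. Pairs across groups were not compared in this way. Counting intervals and floors cover counting error only, at a confidence level of 95%, with a floor of 3 counts over the group.

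Gene symbols were matched to a mouse RefSeq annotation and GENCODE, both on GRCm38, the assembly also called mm10. Of the symbols, 19828 were current, 1497 were an older name of 1 gene, 22 belonged to several genes and 95 had no match. Of the symbols of the counts, 27 had turned into dates. The symbols of the normalized table were used instead, since the constant ratio within each library matches its lines to those of the counts. Positions were assigned to 21301 genes. Clca1 appears under its older symbol Clca3. Genes with near-identical relatives (Ang4, Gbp2, Saa1, Akr1c21, Ly6c1, Iigp1, Clca3 and the H2- genes) may share reads with them, so their values are uncertain. The same holds for 8 named genes that overlap another tested gene on the opposite strand, since the strand setting of the counting is unknown. These are Avil, Ciita, Kdelr3, Muc4, Sh2d7, Tpsg1, Trpm5 and Txndc11.

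Differential expression was tested with the edgeR quasi-likelihood test with robust dispersion (edgeR 4.0.16, limma 3.58.1, R 4.3.3), TMM factors and the default filter on low counts by group. All 16 libraries entered 1 model with a coefficient per group, so the 4 groups shared the estimate of spread. The filter kept 12915 genes, the common dispersion was 0.0137 and the biological coefficient of variation 11.7%. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen, fallen or changed. Adjusted p-values of genes come from this test unless another is named. Values are CPM, the counts per mega-count of TMM-scaled library size, given as mean ± SD with n = 4 per group. Log2 fold changes are given as estimate ± standard error. This standard error was not taken from the fit. It is the absolute log2 change divided by the square root of the F statistic of the test. It is therefore approximate, and for genes with few counts in a group it can be too small. The labels do not say that the libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be partly technical.

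The comparisons were SpdefKO_GC with WT_GC, WT_GC with WT_EC, SpdefKO_GC with SpdefKO_EC, SpdefKO_EC with WT_EC, and the interaction, which is the genotype difference in GC minus that in EC. The groups, tests, gene lists, alternative settings and the rule for naming genes were fixed before the data were examined. In each comparison the rule named Spdef, Muc2, Clca1, Fcgbp, Zg16, Agr2 and Tff3. It also named the genes with the largest changes in each direction, 10 in the first comparison, 6 in the others and 4 in the interaction. For the group comparisons these needed a mean of 5 CPM in the higher group and libraries that did not overlap between the groups. Predicted, clone-named, small RNA, pseudogene and antigen receptor segment genes were left out of this ranking. From each list up to 3 members of at least 1 CPM were added by smallest adjusted p. A result for a gene that the rule named is not reported here.

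The lists covered goblet mucus proteins, secretory lineage transcription factors, ER folding and unfolded protein response, mucin O-glycosylation, ER translocation and vesicle coats, regulated granule exocytosis, proliferation, nuclear respiratory chain genes, interferon response, MHC class II presentation, antimicrobial and mucosal defence, Notch pathway, fatty acid oxidation and ketogenesis, cholesterol synthesis, and tight junction and adhesion. Marker lists covered absorptive colonocytes, stem and crypt-base cells, deep crypt secretory and Paneth cells, enteroendocrine cells, tuft cells, immune cells, and stromal and endothelial cells. Dissociation stress genes, ribosomal protein genes and sex-linked genes served as checks. A list of mitochondrially encoded genes had 0 members in the count table. Lists were tested with camera at a preset correlation of 0.01 on log2 CPM (prior count 2), adjusted over the lists of a comparison. Each was tested again with a correlation estimated from the libraries.

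The tests were checked on simulated counts with known answers over 12915 genes. In the comparison of SpdefKO_GC with WT_GC, 79.1% of genes changed by 1.5-fold were recovered, 95.5% of those changed by 2-fold and 100% of those changed by 4-fold. For SpdefKO_EC with WT_EC the shares were 65.7%, 97.0% and 100%. For WT_GC with WT_EC they were 67.2%, 89.6% and 98.5%, and for SpdefKO_GC with SpdefKO_EC 64.2%, 89.6% and 98.5%. For the interaction they were 34.3%, 77.6% and 98.5%. False calls made up 3.21–5.17% of calls over the 5 comparisons. In each, 66–67 genes were changed at each size, besides a list of 30 raised 2-fold, all at 1 CPM or more in every group. Counts were drawn independently from the dispersions fitted to the data, with no correlation between libraries. In the data 9.53–61.2% of tested genes were called, far more than were changed here. The shares recovered and falsely called may therefore differ in the data.

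Library numbers in the titles are unique, but GC and EC libraries of a genotype carry adjacent numbers (3 and 4, 5 and 6, 7 and 8, 19 and 20 for SpdefKO; 9 and 10, 11 and 12, 13 and 14, 17 and 18 for WT). Deviations from the group means correlated across genes within each such pair (r = 0.125–0.613), and in all 8 pairs the best match of the GC library was its own neighbour. The labels do not state a pairing. The adjacent numbers were therefore also fitted as a block, and blocked values stand beside a result where they change a call.

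Alternatives to the settings above were DESeq2 size factors, upper-quartile factors, the DESeq2 Wald test (DESeq2 1.42.0), limma-voom with quality weights, no low-count filter, a filter at 5 CPM in 4 libraries, removal of the 20 most abundant genes, only the 2 groups compared, glmTreat against a 1.5-fold bound, each library left out in turn and the block. Leaving out each adjacent pair, testing lists with upper-quartile factors and testing them with the block were chosen after seeing the data. Tables were handled and plots drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.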

Results

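Gene expression was measured by RNA sequencing in cells sorted from the distal colon of mice. RedMUC298trTg reporter mice (WT) mark goblet cells, the mucus-secreting cells of the gut, with mCherry. Goblet cells (GC) were collected as mCherry-positive cells and the remaining epithelial cells (EC) as mCherry-negative cells. The second genotype was the same reporter on a background labelled as lacking Spdef (SpdefKO), a transcription factor of secretory cell maturation. Each of the groups WT_GC, WT_EC, SpdefKO_GC and SpdefKO_EC held 4 libraries, named here by group and library number. Libraries held 10085637–17111987 counts over 21442 genes, of which 12915 were tested. The first principal component took 76.2% of the variance and the second 7.52%.

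Spdef, the targeted gene, was measured first in every library. It lies on chromosome 17 at 27714352–27728955 of GRCm38, on the minus strand, in models of up to 7 exons. Spdef was at 296 ± 17.7 CPM in WT_GC and 371 ± 62.2 CPM in SpdefKO_GC. The WT_GC libraries 9, 11, 13 and 18 were at 280.0, 306, 281 and 315 CPM, and the SpdefKO_GC libraries 3, 5, 7 and 19 at 369, 373, 446 and 294 CPM. In EC it was at 2.69 ± 0.809 CPM in WT and 2.15 ± 0.988 CPM in SpdefKO. The WT_EC libraries 10, 12, 14 and 17 were at 2.54, 1.82, 3.77 and 2.64 CPM, and the SpdefKO_EC libraries 4, 6, 8 and 20 at 2.04, 1.89, 3.51 and 1.15 CPM. Spdef did not pass the test between SpdefKO_GC and WT_GC (log2 0.33 ± 0.14, adjusted p = 0.116) or between SpdefKO_EC and WT_EC (log2 -0.28 ± 0.28, adjusted p = 0.559). Without SpdefKO_GC 19 it passed as higher in SpdefKO_GC (log2 0.43, adjusted p = 0.0459; 0.0459–0.286 over all single libraries left out), as it did with limma-voom (adjusted p = 0.0341) and with only the groups compared (adjusted p = 0.0439). The Spdef count was thus not reduced in libraries labelled SpdefKO_GC, while in EC, at low counts, a reduction was neither shown nor excluded. Which part of the gene the allele removes is not given in the sources used here, and a count over the whole gene cannot show it. Every genotype comparison therefore rests on the labels, and SpdefKO stands for libraries labelled SpdefKO.

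**Figure D1:**
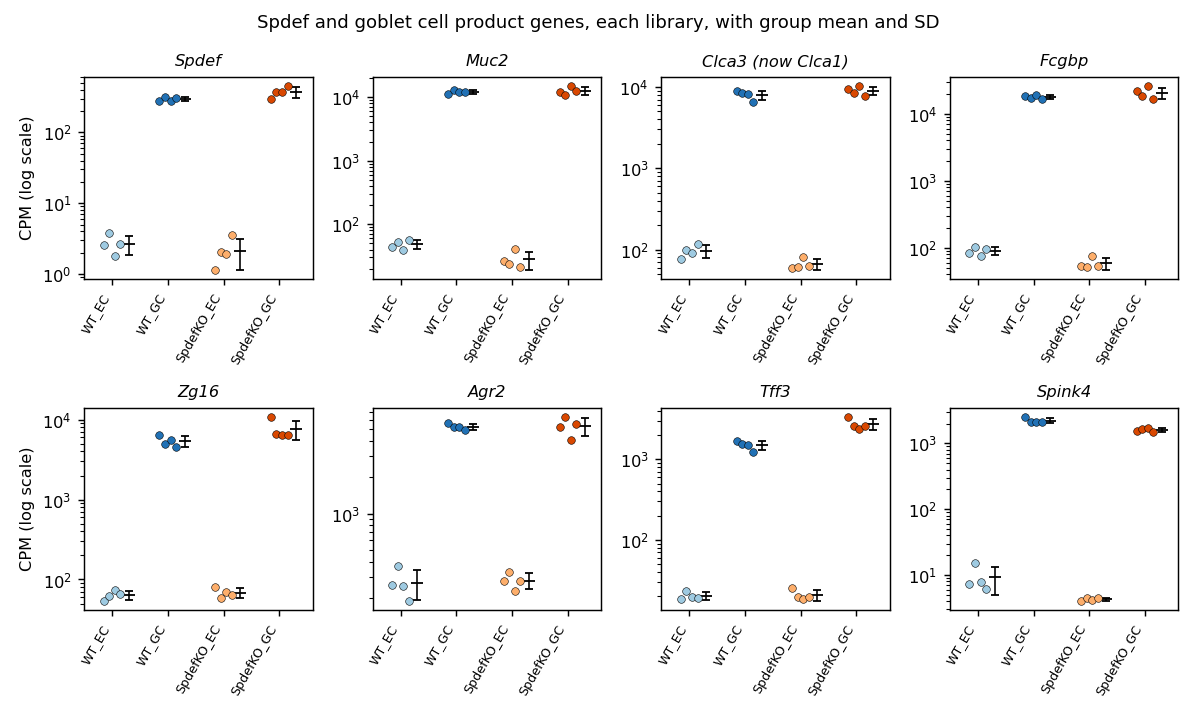
CPM on log axes of Spdef and of genes for goblet cell products in each library (points), with group means and SD (bars, n = 4). Spdef and the other genes were far higher in both GC groups than in both EC groups, and Spdef averaged 296 CPM in WT_GC and 371 CPM in SpdefKO_GC.

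Goblet cells of both genotypes were compared to ask which genes depend on Spdef. Both groups were sorted as mCherry-positive, so goblet cells with too little mCherry to pass the gate are not covered. Muc2, the main secreted mucin of the colon, was at 12087 ± 682 CPM in WT_GC and 12550 ± 1691 CPM in SpdefKO_GC (log2 0.05 ± 0.16, adjusted p = 0.840). By contrast, A4gnt, which adds a terminal N-acetylglucosamine to mucin-type glycans, fell 144-fold in libraries labelled SpdefKO_GC, from 41.96 ± 3.70 to 0.282 ± 0.150 CPM (log2 -7.17 ± 0.23, adjusted p = 9.43e-12). B3gnt6, a synthase of mucin O-glycan cores, fell 28.4-fold from 58.9 ± 6.13 to 2.07 ± 0.203 CPM (log2 -4.83 ± 0.14, adjusted p = 4.21e-14). Enteroendocrine and interferon response genes were among those that rose. In all, 1342 genes rose and 1422 fell by the edgeR test, and 4452 genes had an unadjusted p under 0.05. At least 2-fold changes made up 276 of the higher and 183 of the lower genes. Against a 1.5-fold bound (glmTreat) 260.0 genes passed, and the named genes Zg16, Tff3, Gbp2, Foxa3, Ern2, Txndc11, Sec16a, Slc12a2, Dll1, Cenpe, Mki67, Cox8a and Ndufa7 did not.

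Among Tff3, Zg16, Clca3, Fcgbp and Agr2, other goblet cell products, Tff3 and Zg16 rose and the rest did not pass. Over the whole list of goblet mucus proteins 5 of 15 measured members rose and 3 fell. Tff3, a trefoil peptide of mucus, rose from 1479 ± 193 to 2721 ± 407 CPM (log2 0.88 ± 0.12, adjusted p = 2.59e-05). Zg16, a lectin of mucus that binds bacteria, rose from 5354 ± 835 to 7618 ± 2094 CPM (log2 0.51 ± 0.16, adjusted p = 0.0284). The Zg16 call was lost without WT_GC 11 (adjusted p = 0.0741), WT_GC 18 (0.0659) or SpdefKO_GC 19 (0.0898), with only the groups compared (0.0586) and without the filter on low counts (0.0679). Clca3, the current Clca1, a mucus-processing protease, had a log2 change of 0.17 ± 0.13 (adjusted p = 0.383), and Fcgbp, a mucus component, one of 0.20 ± 0.14 (adjusted p = 0.337). For Agr2, a disulfide isomerase of mucin folding, the change was 0.01 ± 0.16 (adjusted p = 0.973).

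Among the 10 genes with the largest decreases, Creb3l4, a transcription factor anchored in the ER, fell 24.3-fold from 194 to 7.98 CPM (log2 -4.60 ± 0.19, adjusted p = 3.12e-11). Mt3, a metallothionein, fell by 5.67 ± 0.26 on the log2 scale, and Dlk1, a membrane protein related to Notch ligands, by 4.32 ± 0.27. The Golgi membrane protein gene Casc4 fell from 66.5 to 3.51 CPM (log2 -4.24 ± 0.15). Klhl13, a ubiquitin ligase adaptor, Kcne2, a potassium channel subunit, Sowaha and Dzip1l, a ciliary protein, had log2 changes of -4.08 ± 0.31, -3.92 ± 0.40, -3.70 ± 0.31 and -3.38 ± 0.29. Adjusted p ran from 1.61e-12 for Casc4 to 1.38e-06 for Kcne2.

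The largest increase was that of Akr1c21, a hydroxysteroid dehydrogenase, from 0.0790 to 6.49 ± 3.70 CPM (log2 6.15 ± 0.66, adjusted p = 1.60e-05). Nlrc5, the transactivator of MHC class I genes, rose by 4.43 ± 0.97 on the log2 scale (adjusted p = 0.00495; 3.40 without SpdefKO_GC 5), and Cd74, the MHC class II invariant chain, by 3.99 ± 0.64 (adjusted p = 0.000497). Gng2, a G protein subunit, rose from 1.25 to 15.2 ± 2.83 CPM and Abcc8, a subunit of ATP-sensitive potassium channels, from 1.55 to 13.9 CPM (log2 3.61 ± 0.29 and 3.15 ± 0.23). Ang4, an antimicrobial ribonuclease, rose from 22.7 ± 2.93 to 182 ± 64.7 CPM (log2 3.01 ± 0.23, adjusted p = 2.06e-07). The orphan receptor gene Gpr179, the tryptophan-degrading enzyme gene Ido1 and the receptor kinase gene Ret rose by 2.78 ± 0.26, 2.67 ± 0.54 and 2.38 ± 0.20 on the log2 scale. Gbp2, an interferon-induced GTPase, rose by 2.80 ± 0.82 (adjusted p = 0.0287; 1.98 without SpdefKO_GC 5). The Gbp2 call was lost without WT_GC 9 (adjusted p = 0.0612), 11 (0.0721), 13 (0.0842) or 18 (0.0516), without SpdefKO_GC 3 (0.0506) or 5 (0.0990), without the filter on low counts (0.0529) and with limma-voom (0.107).

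**Figure D2:**
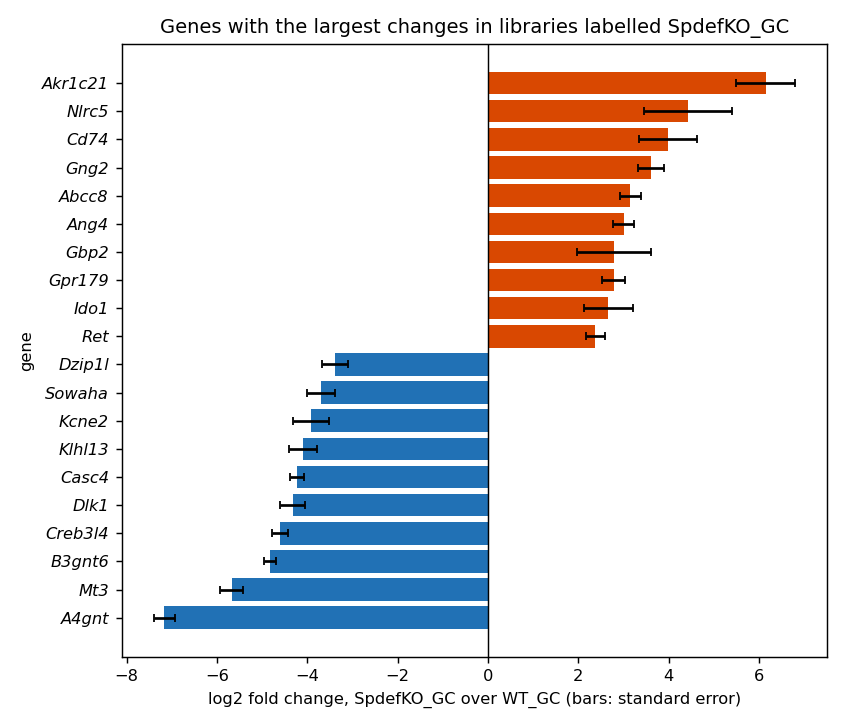
Log2 fold change of SpdefKO_GC over WT_GC (x axis) for the 10 largest increases and the 10 largest decreases under the naming rule (n = 4 per group). Bars are the approximate standard errors. The changes run from -7.17 for A4gnt to 6.15 for Akr1c21.

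Genes of mucin O-glycosylation fell more often than they rose in goblet cells labelled SpdefKO. Of 47 measured members 21 fell and 3 rose (4 higher and 22 lower adjusted over the list alone; median log2 -0.28, camera adjusted p = 1.85e-05), with an adjusted p = 0.161 with an estimated correlation. Galnt12, which starts O-glycan chains, fell from 327 to 112 CPM (log2 -1.54 ± 0.11, adjusted p = 2.32e-08), and B4galnt2, which adds N-acetylgalactosamine to glycan ends, from 235 to 118 CPM (log2 -0.996 ± 0.09, adjusted p = 2.01e-07). In ER translocation and vesicle coats 12 of 60 members fell and 4 rose (4 and 13 adjusted over the list alone; camera adjusted p = 0.0221, and adjusted p = 0.642 with an estimated correlation). Sec16a, a scaffold of ER exit sites, fell by 0.60 ± 0.06 on the log2 scale. ER folding and the unfolded protein response had 8 lower and 3 higher members of 45 (also 8 and 3 adjusted over the list alone; camera adjusted p = 0.0707). These included Ern2, the ER stress sensor of goblet cells, which fell from 427 to 243 CPM (log2 -0.81 ± 0.09, adjusted p = 2.21e-06), and Txndc11, a thioredoxin-domain protein (log2 -0.83 ± 0.10).

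Enteroendocrine markers, genes of the hormone-secreting cells, rose in goblet cells labelled SpdefKO. Of 24 measured markers 18 rose and 1 fell, both over all genes and adjusted over the list alone (median log2 1.31, camera adjusted p = 9.14e-10; adjusted p = 0.246 with an estimated correlation). Chgb, a granin of secretory granules, rose from 47.4 to 132 CPM (log2 1.48 ± 0.15, adjusted p = 1.97e-06), Gcg, the proglucagon gene, from 10.2 to 32.3 CPM (log2 1.67 ± 0.18, adjusted p = 6.12e-06), and Tph1, the enzyme of serotonin synthesis, by 1.58 ± 0.21. The 20 secretory lineage transcription factors had 4 higher and 2 lower members (6 and 3 adjusted over the list alone; camera adjusted p = 0.480). Neurog3, which specifies enteroendocrine cells, rose from 0.280 to 1.97 CPM (log2 2.70 ± 0.43, adjusted p = 0.000192; 3.33 without WT_GC 11), and Foxa3, a goblet cell transcription factor, fell from 159 to 91.0 CPM (log2 -0.81 ± 0.12, adjusted p = 0.000104). Absorptive colonocyte markers also rose, 22 of 41 with 5 lower (25 and 6 adjusted over the list alone; median log2 0.38, camera adjusted p = 3.70e-05; adjusted p = 0.613 with an estimated correlation). Guca2a and Guca2b, the guanylin and uroguanylin genes, rose by 1.10 ± 0.08 and 1.43 ± 0.12. Slc9a3, a sodium-hydrogen exchanger, rose from 3.98 to 13.7 CPM, against 250.4 CPM in WT_EC.

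Interferon response genes rose as well, 20 of 39 with 3 lower (29 and 3 adjusted over the list alone; median log2 1.01, camera adjusted p = 2.91e-08; adjusted p = 0.613 with an estimated correlation). Oas2 and Oas3, sensors of double-stranded RNA, rose by 1.94 ± 0.20 and 1.69 ± 0.24 on the log2 scale. Of 9 MHC class II presentation genes 5 rose (6 adjusted over the list alone; camera adjusted p = 0.000908; adjusted p = 0.601 with an estimated correlation), among them H2-Aa (log2 3.94 ± 0.70) and H2-Eb1 (log2 3.08 ± 0.48). H2-Aa and H2-Eb1 lie within 20 Mb of Spdef. Immune cell markers moved the same way, with 3 of 13 higher (3 adjusted over the list alone; median log2 1.07, camera adjusted p = 0.0234; adjusted p = 0.642 with an estimated correlation), including Itgam, an integrin of myeloid cells (log2 1.27 ± 0.22). The interferon medians of the SpdefKO_GC libraries were unequal, at 1.05, 1.62, 0.44 and 0.32 on the log2 scale over the WT_GC mean for libraries 3, 5, 7 and 19.

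Of 40 proliferation genes 7 rose and 0 fell in goblet cells labelled SpdefKO (12 and 0 adjusted over the list alone; median log2 0.41, camera adjusted p = 0.000298; adjusted p = 0.642 with an estimated correlation). The libraries were uneven, with list medians of 0.84, -0.26, 0.63 and 0.20 on the log2 scale over the WT_GC mean for SpdefKO_GC 3, 5, 7 and 19, against -0.27 to 0.19 in WT_GC. Mki67, a marker of cycling cells, rose from 470.01 to 816 CPM (log2 0.80 ± 0.13) and Cenpe, a mitotic kinesin, by 0.87 ± 0.13. Nuclear respiratory chain genes fell, 23 of 76 with 0 higher (26 and 0 adjusted over the list alone; median log2 -0.15, camera adjusted p = 1.42e-06), as did 12 of 76 ribosomal protein genes (8 adjusted over the list alone; camera adjusted p = 0.00132). Both missed the threshold with an estimated correlation (adjusted p = 0.642 with an estimated correlation for each). Cox8a and Ndufa7 fell by 0.38 ± 0.06 and 0.55 ± 0.10 on the log2 scale, and Ndufa7 lies within 20 Mb of Spdef.

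The remaining lists did not pass in goblet cells. Goblet mucus proteins had 5 higher and 3 lower of 15 (5 and 3 adjusted over the list alone; median log2 0.05, camera adjusted p = 0.202). Muc4, a membrane-bound mucin, rose from 184 to 573 ± 161 CPM (log2 1.64 ± 0.20, adjusted p = 2.85e-05). None of 20 tuft cell markers passed the edgeR test (0 also adjusted over the list alone; median log2 -0.18, mean log2 -0.06, camera direction up, adjusted p = 0.996). Stem and crypt-base markers had 2 higher and 5 lower of 18 (camera adjusted p = 0.147), including Slc12a2, a chloride transporter (log2 -0.83 ± 0.09). Deep crypt secretory and Paneth markers had 2 higher and 3 lower of 10 (camera adjusted p = 0.996), among them Dll1, a Notch ligand of secretory progenitors (log2 0.84 ± 0.09). Regulated granule exocytosis had 4 higher and 5 lower of 24 (adjusted p = 0.996), fatty acid oxidation 2 and 6 of 29 (0.0859), cholesterol synthesis 3 and 2 of 25 (0.222), tight junction and adhesion 8 and 3 of 25 (0.0963), the Notch pathway 1 and 0 of 17 (0.547) and stromal markers 1 and 0 of 7 (0.127). Antimicrobial and mucosal defence had 1 higher and 4 lower of 27 (adjusted p = 0.996, camera direction down, median log2 0.07), among them Saa1, an acute-phase protein, which fell from 109 to 35.5 CPM. Dissociation stress genes had 3 higher and 2 lower of 21 (camera adjusted p = 0.683), and 0 of 4 sex-linked genes passed.

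**Figure D3:**
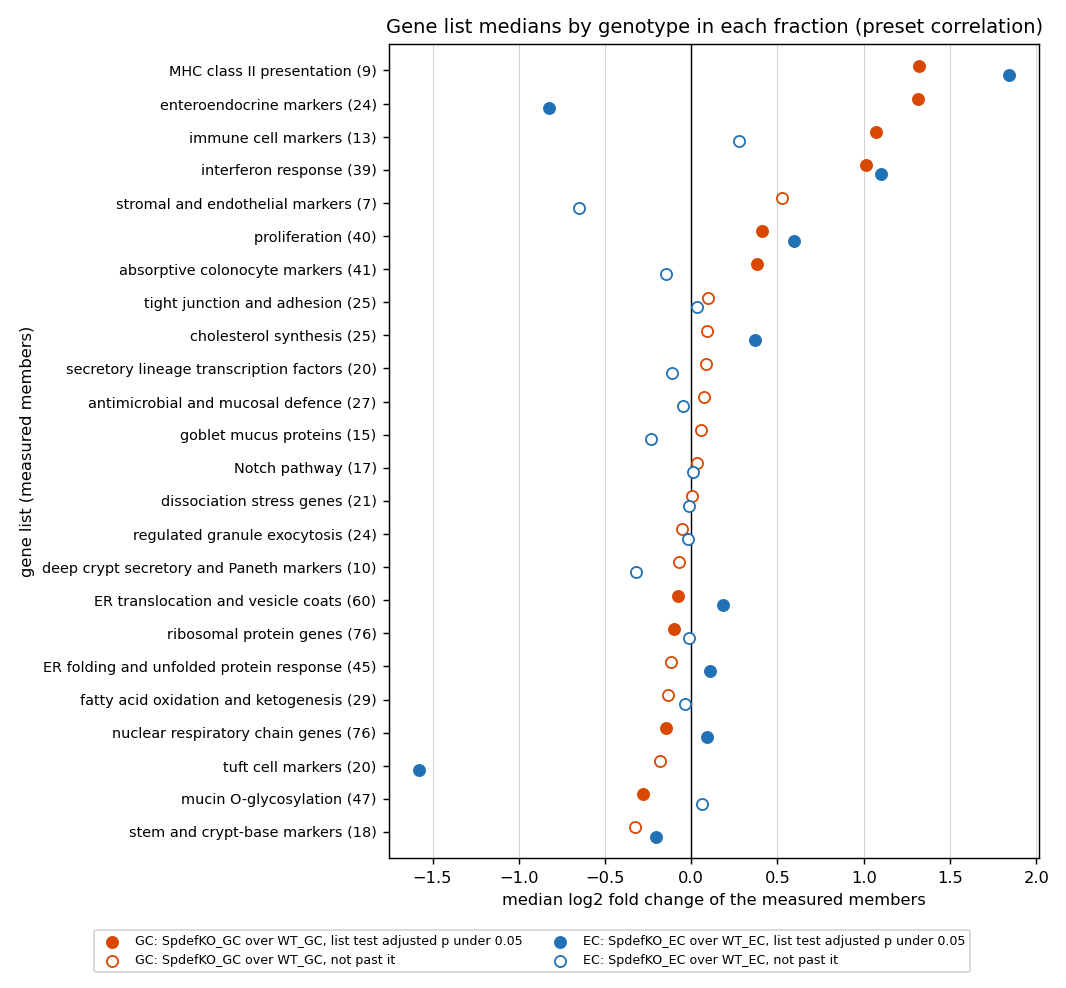
Median log2 fold change (x axis) of the measured members of each gene list (y axis, number of members in brackets) for SpdefKO_GC over WT_GC and SpdefKO_EC over WT_EC, filled where camera with the preset correlation passed. Enteroendocrine markers lay at 1.31 in GC and -0.83 in EC, and tuft cell markers at -0.18 in GC and -1.58 in EC.

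WT_GC and WT_EC were compared to define the goblet cell profile of the reporter mice. Goblet cell products were far higher in it. Muc2 rose 250-fold, from 48.4 CPM in WT_EC to 12087 CPM in WT_GC (log2 7.96 ± 0.22, adjusted p = 2.40e-15), Fcgbp by 7.63 ± 0.19 on the log2 scale and Tff3 by 6.19 ± 0.15. Absorptive genes were depleted, with Slc9a3 63.2-fold lower in WT_GC (log2 -5.98 ± 0.20, adjusted p = 7.38e-14) and Car4, a carbonic anhydrase of the brush border, at 32.4 ± 12.6 against 1691 ± 76.1 CPM (log2 -5.72 ± 0.27, adjusted p = 4.98e-11). In all, 4007 genes rose and 3894 fell, of which 1157 and 1642 by at least 2-fold, and 3390 passed against a 1.5-fold bound. Upper-quartile factors gave 4859 higher and 3457 lower, a share of 58.4% higher against 50.7%.

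The 6 genes ranked highest in WT_GC included Rian, a long noncoding RNA (log2 9.30 ± 0.24, from 0.305 to 198 CPM), Tpsg1, a membrane tryptase (8.52 ± 0.17) and A4gnt (8.50 ± 0.27). Sdr16c6, a retinol dehydrogenase family member, had 410 counts in WT_GC and 0 in WT_EC and was at least 135-fold higher in WT_GC, against the floor over the group. Retnlb, a goblet cell antimicrobial protein, had 1813 against 3 counts, a ratio of 595 (203–2890). This ratio rests on WT_EC 17, which held all of the WT_EC counts (the fitted log2 change of 8.92 became 11.77 without it). Pla2g2a, a secreted phospholipase, had 943 against 2 counts, a ratio of 465 (128–3842). Clca3, Zg16, Agr2 and Spdef rose by 6.38, 6.40, 4.30 and 6.77 on the log2 scale. The lowest in WT_GC, after Slc9a3, were Il1b, a cytokine (log2 -5.92 ± 0.46; -6.60 without WT_GC 18), Mal (-5.84 ± 0.44), Slc34a2, a phosphate transporter (-5.76 ± 0.19), Creb3l3, a lipid-regulating transcription factor (-5.72 ± 0.28) and Car4.

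Lists of the secretory pathway were higher in WT_GC. They included 14 of 15 goblet mucus proteins (1 lower; median log2 6.35, camera adjusted p = 6.26e-10), 41 of 45 ER folding genes (42 adjusted over the list alone; 5.63e-13), 35 of 47 O-glycosylation genes (10 lower; 1.86e-07) and 10 of 10 deep crypt secretory markers (1.86e-07). These held with an estimated correlation (adjusted p = 0.00906, 0.0490, 0.0199 and 0.0172). ER translocation and vesicle coats had 54 higher of 60 (2 lower; camera adjusted p = 1.25e-16; adjusted p = 0.0608 with an estimated correlation) and granule exocytosis 14 of 24 (5 lower; 0.00248; adjusted p = 0.128 with an estimated correlation). Absorptive colonocyte markers were lower, 38 of 41 (3 higher; camera adjusted p = 5.63e-18; adjusted p = 0.0405 with an estimated correlation), as were 22 of 24 enteroendocrine markers (1 higher; median log2 -2.10, camera adjusted p = 6.78e-07; adjusted p = 0.128 with an estimated correlation) and 9 of 13 immune markers (3 higher; 0.0120; adjusted p = 0.311 with an estimated correlation). Of 20 tuft cell markers 2 rose and 3 fell (camera adjusted p = 0.434). Ribosomal protein genes, a check between fractions purified on different columns, were also higher in WT_GC, 66 of 76 with 2 lower (median log2 0.34, camera adjusted p = 3.09e-08; adjusted p = 0.321 with an estimated correlation). With adjacent library numbers as a block, proliferation (adjusted p = 0.0217) and MHC class II presentation (0.0222) also passed, against 0.306 and 0.0527 without it (adjusted p = 0.850 and 0.486 with an estimated correlation).

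SpdefKO_GC and SpdefKO_EC were compared in the same way. Goblet cell products were again far higher, with Muc2 447-fold higher in libraries labelled SpdefKO_GC, at 12550 against 28.1 CPM (log2 8.80 ± 0.22, adjusted p = 2.01e-15), Fcgbp at a log2 change of 8.46 ± 0.20 and Spink4, a protease inhibitor of goblet cells, at 1602 ± 87.8 against 4.28 CPM (8.54 ± 0.22). Mptx1, a secreted pentraxin, was at 2015 ± 447 against 5.08 CPM (8.63 ± 0.38) and Nov, a matricellular protein, at 1251 ± 269 against 3.30 CPM (8.56 ± 0.26). Aqp8, a water channel of absorptive cells, fell most, from 1110.4 to 34.0 CPM (log2 -5.03 ± 0.20, adjusted p = 1.58e-12). In all, 3619 genes were higher and 3666 lower in SpdefKO_GC, 1140 and 1311 of them by at least 2-fold, and 2892 passed against a 1.5-fold bound. Upper-quartile factors gave 4752 higher and 3047 lower, a share of 60.9% higher against 49.7%, and moved the median of all genes by 0.11 on the log2 scale.

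Tff3, Clca3, Zg16, Agr2 and Spdef rose by 7.05, 7.08, 6.81, 4.26 and 7.37 on the log2 scale. After Aqp8, the lowest genes were Prss30 (log2 -4.79 ± 0.17), Slc9a3 (-4.77 ± 0.18), Car4 (-4.72 ± 0.26), Tpm2, a tropomyosin (-4.69 ± 0.20), and Mal (-4.64 ± 0.42). Of 15 goblet mucus proteins 14 were higher (1 lower; median log2 6.57, camera adjusted p = 1.43e-11; adjusted p = 0.00432 with an estimated correlation), and of 47 O-glycosylation genes 33 (11 lower; median log2 0.74, camera adjusted p = 1.43e-05; adjusted p = 0.0482 with an estimated correlation). Absorptive markers had 38 of 41 lower (3 higher; camera adjusted p = 1.42e-17; adjusted p = 0.0482 with an estimated correlation). Tuft cell markers were higher, 15 of 20 with 2 lower (16 and 2 adjusted over the list alone; median log2 1.22, camera adjusted p = 0.0058; adjusted p = 0.406 with an estimated correlation). Enteroendocrine markers had 2 higher and 4 lower of 24 (median log2 -0.12, camera adjusted p = 0.963), and 4 higher and 3 lower with upper-quartile factors. Respiratory chain genes had 59 of 76 lower (1 higher; camera adjusted p = 5.55e-08; adjusted p = 0.406 with an estimated correlation). Ribosomal protein genes had 53 of 76 higher and 2 lower (median log2 0.25, camera adjusted p = 4.48e-06; adjusted p = 0.406 with an estimated correlation). With adjacent library numbers as a block, stem markers, proliferation and dissociation stress genes also passed (adjusted p = 0.0452 each; adjusted p = 0.406, 0.986 and 0.843 with an estimated correlation).

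SpdefKO_EC and WT_EC were compared to find genotype differences outside goblet cells. Tuft cell markers, genes of the chemosensory epithelial cells, fell in libraries labelled SpdefKO_EC. Trpm5, their taste-signalling channel, fell from 11.4 to 2.79 CPM (log2 -2.003 ± 0.24, adjusted p = 3.73e-05), Avil, an actin-binding protein, by 1.38 ± 0.19 on the log2 scale and Hpgds, a prostaglandin synthase, by 1.10 ± 0.15. Interferon response genes rose, among them Oas3 (log2 1.58 ± 0.19, adjusted p = 3.67e-05) and Ifit2, an antiviral effector (1.81 ± 0.27). In all, 787 genes rose and 844 fell by the edgeR test, 101 and 270 of them by at least 2-fold. The count of 1631 fell to 1006 without WT_EC 17 and to 940.0 without SpdefKO_EC 4, was 1075 with only the groups compared and 3031 with limma-voom, and was 133 against a 1.5-fold bound, which the named genes Iigp1, Nlrc5, Ciita, Slc15a2, Muc2, Clca3, Fcgbp, Spink4, Kdelr3, Sec24d, Cenpe, Kif23, Chgb, Idi1 and Fdps missed. Upper-quartile factors gave 533 higher and 1079 lower, a share of 33.1% higher against 48.3%.

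The goblet cell products remaining in EC were at low levels, and Muc2 fell from 48.4 to 28.1 CPM (log2 -0.78 ± 0.17, adjusted p = 0.00715), Fcgbp by 0.62 ± 0.15, Spink4 by 1.09 ± 0.22 and Clca3 by 0.53 ± 0.14 on the log2 scale. The Clca3 call (adjusted p = 0.0146) was lost without WT_EC 17 (log2 -0.43, adjusted p = 0.0592). Zg16, Agr2 and Tff3 had log2 changes of 0.09, 0.06 and 0.03 (adjusted p = 0.750, 0.859 and 0.924). H2-Bl, an MHC class I-like gene within 20 Mb of Spdef, rose from 1.497 to 17.6 CPM (log2 3.56 ± 0.20, adjusted p = 4.52e-09), with Nlrc5 (3.36 ± 0.74), AI747448 (3.30 ± 0.37) and Ly6c1, a surface antigen (3.23 ± 0.44). Iigp1, an interferon-induced GTPase (4.82 ± 1.38, adjusted p = 0.0376), and Ciita, the MHC class II transactivator (2.73 ± 0.81, adjusted p = 0.0400), also rose. Among the largest decreases were Abcg1, a cholesterol exporter (log2 -2.59 ± 0.31, from 21.9 to 3.56 CPM), Sh2d7 (-2.47 ± 0.39), Dnahc5, an axonemal dynein (-2.23 ± 0.30), Asb11 (-2.23 ± 0.21), Fndc5 (-2.20 ± 0.20) and Slc15a2, a peptide transporter (-2.95 ± 0.89, adjusted p = 0.0437). Log2 changes moved to 4.18 and 1.81 for Iigp1 and Ciita without SpdefKO_EC 6 and to -4.16 for Slc15a2 without SpdefKO_EC 8. The calls of Iigp1, Ciita and Slc15a2 were each lost when certain single libraries were left out. Without WT_EC 10, 12, 14 or 17 or SpdefKO_EC 4 or 6 the adjusted p of Iigp1 was 0.0853, 0.0877, 0.0834, 0.0905, 0.0885 and 0.0689, and that of Ciita 0.0821, 0.0717, 0.0890, 0.101, 0.0787 and 0.118. For Slc15a2 it was 0.0792, 0.0918 and 0.0853 without WT_EC 10, 12 or 17, and 0.121, 0.0739 and 0.0601 without SpdefKO_EC 4, 6 or 20. All 3 calls were also lost without the filter on low counts (adjusted p = 0.0667, 0.0931 and 0.0936) and with only the groups compared (0.0503, 0.0572 and 0.0522), that of Iigp1 with limma-voom (0.190) and that of Slc15a2 with the DESeq2 Wald test (0.114).

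Of 20 tuft cell markers 12 fell and 0 rose (16 and 0 adjusted over the list alone; median log2 -1.58, camera adjusted p = 7.54e-12; adjusted p = 0.247 with an estimated correlation). Of 24 enteroendocrine markers 10 fell and 0 rose (16 and 0 adjusted over the list alone; median log2 -0.83, camera adjusted p = 5.71e-10; adjusted p = 0.247 with an estimated correlation). Chga and Chgb, granins, fell from 101 to 45.6 CPM and from 340.05 to 167 CPM (log2 -1.14 ± 0.15 and -1.03 ± 0.14), and Sst, the somatostatin gene, by 1.63 ± 0.26. Interferon response genes had 22 of 39 higher and 0 lower (34 and 1 adjusted over the list alone; median log2 1.10, camera adjusted p = 7.54e-12; adjusted p = 0.272 with an estimated correlation), and MHC class II presentation 7 of 9 higher and 1 lower (8 and 1 adjusted over the list alone; camera adjusted p = 0.000371; adjusted p = 0.272 with an estimated correlation), such as H2-Ab1 (log2 1.99 ± 0.28). Immune markers had 2 of 13 higher (median log2 0.27, camera adjusted p = 0.182).

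Cholesterol synthesis genes rose in libraries labelled SpdefKO_EC, 16 of 25 with 0 lower (19 and 0 adjusted over the list alone; median log2 0.37, camera adjusted p = 3.21e-11; adjusted p = 0.247 with an estimated correlation), with Idi1 and Fdps, enzymes of isoprenoid synthesis, at log2 changes of 0.61 ± 0.10 and 0.70 ± 0.12. ER translocation and vesicle coats had 15 of 60 higher (20 adjusted over the list alone; camera adjusted p = 2.07e-09; adjusted p = 0.247 with an estimated correlation), with Kdelr3, an ER retrieval receptor, at 1.06 ± 0.16 and Sec24d, a coat protein, at 0.43 ± 0.07. Proliferation genes had 12 of 40 higher (19 adjusted over the list alone; median log2 0.60, camera adjusted p = 3.72e-06; adjusted p = 0.616 with an estimated correlation), including Cenpe (0.85 ± 0.13) and Kif23, a kinesin of cytokinesis (0.66 ± 0.15). Their list medians over the WT_EC mean were 0.85, -0.11, 0.88 and 0.22 on the log2 scale for SpdefKO_EC 4, 6, 8 and 20, against -0.25 to 0.36 in WT_EC, so only libraries 4 and 8 lay above the WT range. Stem markers had 4 of 18 lower (5 adjusted over the list alone; camera adjusted p = 0.000351; adjusted p = 0.247 with an estimated correlation). Absorptive markers had 8 higher and 7 lower of 41 (median log2 -0.14, camera adjusted p = 0.277), and 7 and 8 with DESeq2 size factors. Within them Mep1a, a brush border protease, fell from 569 to 281 CPM (log2 -1.02 ± 0.11, adjusted p = 1.92e-05), and it lies within 20 Mb of Spdef. Cyp2c55, a cytochrome P450, fell from 1037 to 428 CPM (log2 -1.28 ± 0.19, adjusted p = 0.000604).

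**Figure D4:**
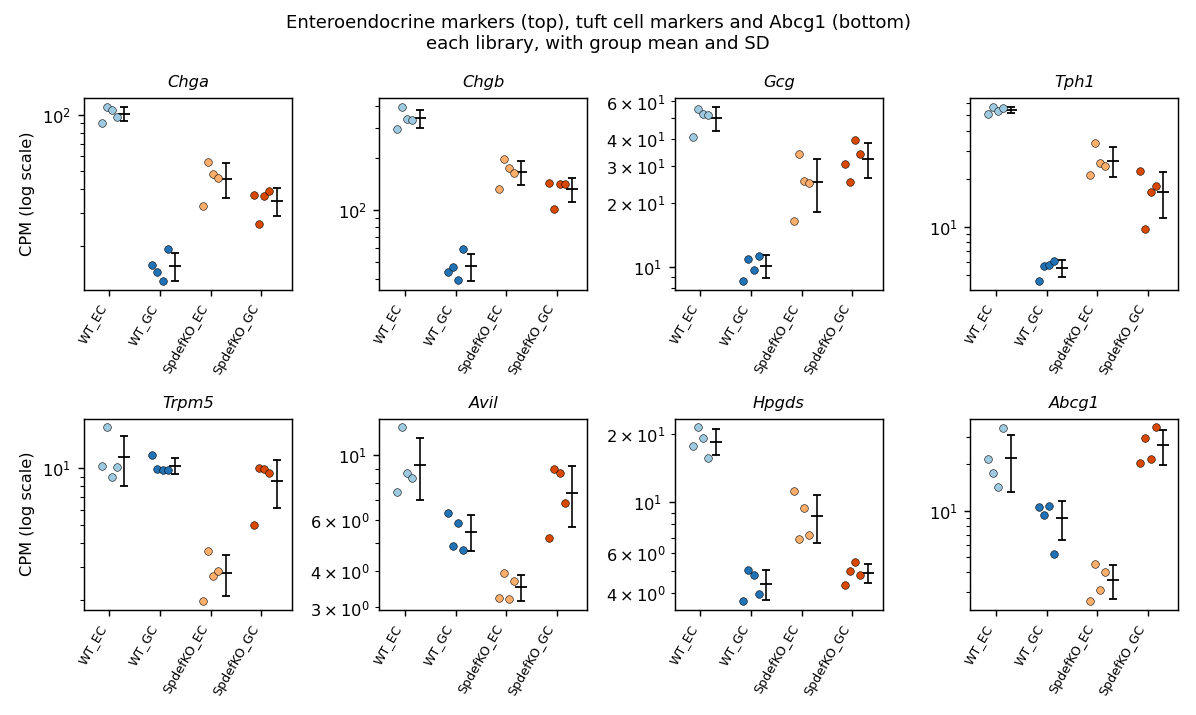
CPM on log axes of enteroendocrine markers (top), tuft cell markers and Abcg1 (bottom) in each library (points), with group means and SD (bars, n = 4). Chgb went from 340.05 CPM in WT_EC to 167 CPM in SpdefKO_EC, and from 47.4 CPM in WT_GC to 132 CPM in SpdefKO_GC.

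The interaction asked whether the genotype difference was unlike in GC and EC. It was for enteroendocrine markers, of which 19 of 24 had a higher genotype change in GC than in EC and 0 a lower one (21 and 0 adjusted over the list alone; median log2 2.09, camera adjusted p = 2.96e-20; adjusted p = 0.0517 with an estimated correlation). Chgb, Chga and Gcg had interaction values of 2.502 ± 0.20, 2.29 ± 0.22 and 2.65 ± 0.25 on the log2 scale (adjusted p = 1.92e-06, 4.39e-06 and 4.77e-06). Among the genes with the largest values were Abcg1 (4.17 ± 0.42), Gng2 (3.95 ± 0.48), Abcc8 (3.65 ± 0.34) and Rab3c, a vesicle GTPase (3.22 ± 0.36). Kcne2, B3gnt6, Casc4 and Creb3l4 had the most negative ones (-5.68 ± 0.92, -4.72 ± 0.27, -4.01 ± 0.26 and -3.87 ± 0.32), that of Kcne2 moving to -6.52 without WT_EC 12. In all, 630 genes had a positive and 601 a negative interaction (291 and 76 beyond 2-fold), 3329 genes passed with adjacent library numbers as a block, and 146 passed against a 1.5-fold bound, which Muc2, Clca3, Fcgbp, Tff3, Copb1 and Sec16a missed. Upper-quartile factors gave 715 positive and 479 negative, a share of 59.9% positive against 51.2%.

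Muc2, Fcgbp, Clca3 and Tff3 had positive interactions of 0.84 ± 0.23, 0.83 ± 0.20, 0.70 ± 0.19 and 0.85 ± 0.18 on the log2 scale (adjusted p = 0.0308, 0.0149, 0.0231 and 0.00464). Of these, Muc2, Fcgbp and Clca3 did not pass in GC and fell in EC, where their levels were far below those in GC. Tff3 rose in GC and did not pass in EC. The Muc2 call was lost without WT_EC 17 (adjusted p = 0.0683), WT_GC 9 (0.0504) or 13 (0.0628), SpdefKO_EC 4 (0.0595) or 8 (0.0544), SpdefKO_GC 5 (0.0630) and without the filter on low counts (0.0811), and that of Clca3 without WT_EC 17 (0.0519). Zg16, Agr2 and Spdef did not pass (adjusted p = 0.285, 0.933 and 0.261). Tuft cell markers had 9 of 20 higher (13 adjusted over the list alone; median log2 1.39, camera adjusted p = 4.01e-09; adjusted p = 0.183 with an estimated correlation), such as Avil (1.83 ± 0.27) and Trpm5 (1.74 ± 0.32). O-glycosylation genes had 15 of 47 lower and 1 higher (19 and 2 adjusted over the list alone; camera adjusted p = 2.20e-06; adjusted p = 0.0517 with an estimated correlation), with Galnt12 at -1.64 ± 0.16. Vesicle coats had 16 of 60 lower and 1 higher (24 and 1 adjusted over the list alone; camera adjusted p = 6.75e-11; adjusted p = 0.210 with an estimated correlation), with Copb1 and Sec16a, coat components, at -0.52 ± 0.08 each. Absorptive markers had 9 of 41 higher and 1 lower (13 and 1 adjusted over the list alone; camera adjusted p = 1.12e-06; adjusted p = 0.292 with an estimated correlation), led by Guca2a (1.34 ± 0.11) and Guca2b (1.95 ± 0.20). Interferon response, MHC class II and proliferation lists did not pass (camera adjusted p = 0.911, 0.568 and 0.813).

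The goblet signature, 474 genes at least 4-fold higher in WT_GC than in WT_EC, was followed into SpdefKO_GC. Of these, 162 fell and 76 rose, with a median log2 change of -0.257. Both comparisons share the WT_GC libraries. Unchanged groups simulated from the means of these libraries gave 0 lower and 0 higher genes in 12 simulations, with medians of -0.00525 to 0.0139. They carry over any deviation of those means, so they cannot show what sharing the libraries does. With the WT_GC libraries split so that one part defined the genes and the other tested them, 130–152 of 496–509 genes fell and 42–59 rose. Genotype changes were also compared between fractions, which share no library. There were 265 genes higher in both (81.8 if the lists were independent) and 206 lower in both (92.9). Another 83 rose in GC and fell in EC (87.7 if independent), and 33 fell in GC and rose in EC (86.7). Libraries with adjacent numbers deviate together across the fractions (r = 0.125–0.613), which by itself can raise the overlap, so the values for independent lists are not those to be had without a genotype change.

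**Figure D5:**
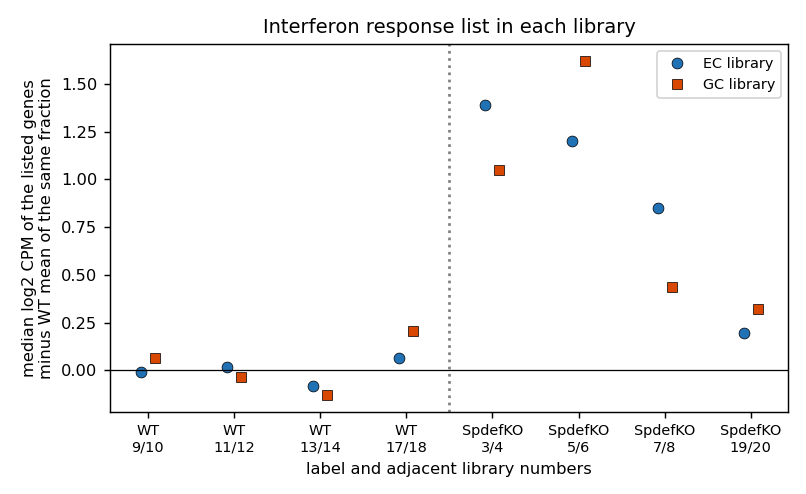
Median log2 CPM of the interferon response list in each library minus the WT mean of the same fraction (y axis), by adjacent library numbers (x axis), for EC and GC. SpdefKO pairs averaged 1.22 (3/4), 1.41 (5/6), 0.643 (7/8) and 0.260 (19/20), and WT pairs -0.104 to 0.138.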

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

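The tests of the MHC genes near Spdef, of the sort in the enteroendocrine pattern, of the interferon pattern, and of splits with the block were chosen only after those results were seen.

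Other splits of the same libraries were tried for each comparison, and in all 5 the labelled split gave the most genes. This does not exclude chance. For the group comparisons 1 of 35 is the smallest share possible, and each other split mixes the labelled groups, which widens its spread. The labels also do not say that the libraries came from separate mice. For SpdefKO_GC with WT_GC the labelled split gave 2764 genes and the highest of the other splits 0, so 1 of 35 splits was as large. For WT_GC with WT_EC it gave 7901 against 0 (1 of 35), for SpdefKO_GC with SpdefKO_EC 7285 against 466 (1 of 35), and for SpdefKO_EC with WT_EC 1631 against 266 (1 of 35). For the interaction it gave 1231 against 497 (1 of 100 drawn), and with the block 3329 against 0 (1 of 35). In both comparisons of GC with EC, the 7 other splits that part all 4 adjacent pairs gave at most 0 genes, and 7 are too few to exclude chance. The split with 466 genes set libraries 3, 4, 7 and 8 against the other SpdefKO libraries and so follows adjacent numbers.

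The first pattern concerns genes near Spdef. Within 20 Mb of Spdef on chromosome 17, 37 of 469 tested genes (7.89%) changed with genotype in the same direction in both fractions, against 432 of 12370 elsewhere (3.49%; odds ratio 2.37, interval 1.62–3.37, Fisher exact p = 1.23e-05), among them Glo1 (log2 1.09 in GC and 1.30 in EC) and Cacna1h (-1.94 and -1.25). Flanking DNA from another strain, carried along with the allele, may account for part of it and met its test, although 2 of 186 other windows of this width held a share as high. Mep1a, Ndufa7, H2-Aa, H2-Eb1 and H2-Bl, given above as examples of other changes, were among the 37 genes too. Cacna1h overlaps Tpsg1 on the opposite strand, so its values are uncertain while the strand setting of the counting is unknown. The span of H2- genes held 22 of the 37 genes. Without the H2- genes themselves and the interferon and MHC class II lists the count was 25 of 444 (odds ratio 1.71, interval 1.08–2.60, Fisher exact p = 0.0161), and 18 of the other windows held a share as high. Without the whole span and these lists it was 15 of 345 (odds ratio 1.31, interval 0.716–2.21, Fisher exact p = 0.292), and 44 of the other windows held a share as high. Interferon-regulated MHC genes of the region and strain DNA in the same span cannot be told apart, because this interval holds 1 and overlaps that of all genes. Of the H2- genes in the span, 8 were higher in both fractions and 4 lower, namely H2-T23 (log2 -1.84 in GC and -0.89 in EC), H2-T3 (-1.46 and -2.01), H2-Q1 (-1.49 and -0.83) and H2-Ke6 (-0.42 and -0.41). They were picked by name, so not each need be an MHC gene. A rise driven by interferon alone does not give the falls of H2-T23, H2-T3 and H2-Q1. An effect of Spdef on its neighbours stays open and untested.

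The second pattern concerns enteroendocrine markers, lower in libraries labelled SpdefKO_EC and higher in those labelled SpdefKO_GC. To reach their SpdefKO_GC level by carry-over they would need a median of 74.4% SpdefKO_EC RNA (64.2–89.7, 13 markers), whereas absorptive markers allow 2.17% (0.919–3.13, 35 markers), which argues against more mCherry-negative cells of every type in the goblet sort. These intervals, and those of list medians below, resample the listed genes and leave out the spread between libraries. More genes were detected in each SpdefKO_GC library (17221–18056) than in any WT_GC library (16553–17105). The source of this difference was not tested. Of 10 markers that fell in EC, 8 rose in GC, Sst and Pcsk1 being the exceptions, but so did 10 of the 14 other markers (odds ratio 1.57, interval 0.170–21.6). Enteroendocrine cells sorted with the mCherry-positive cells and goblet cells that express these genes themselves cannot be told apart, since bulk libraries do not separate the cells, and no biological explanation was tested.

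The third pattern concerns interferon response genes, higher in both fractions of libraries labelled SpdefKO. In EC immune markers had a median log2 change of 0.27 (-0.176 to 0.532) and the interferon list one of 1.10 (0.673 to 1.34). For SpdefKO_EC 4, 6, 8 and 20 the immune medians over the WT_EC mean were 0.20, 0.57, 0.46 and -0.14, and the interferon medians 1.39, 1.20, 0.85 and 0.20. The interferon median was the higher in each library, which argues against immune cells as the only source in EC. In GC the same explanation cannot be told apart, because the immune median of 1.07 (0.0220 to 1.58) overlaps that of the list (1.01, 0.691 to 1.41). Strain DNA around Spdef cannot be told apart from an effect of Spdef itself. Of 39 members 36 lie away from it, with a lower limit of 0.57 on the log2 scale for their median in EC, so leaving out the others decides nothing, and a variant acting on distant genes was not tested. The list averaged 1.22, 1.41, 0.643 and 0.260 in the SpdefKO pairs 3/4, 5/6, 7/8 and 19/20, against -0.104 to 0.138 in the WT pairs. All SpdefKO pairs lay above the WT pairs, the lowest at 0.26, as an effect of the allele would give. They were unequal, however, with an SD between pairs of 0.528 against 0.100 in WT, and litter, cage and health are not given in the labels used here. A difference between the mice other than the allele therefore cannot be told apart from an effect of Spdef.

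Single libraries stood apart from the other 3 of their group in 33 of 516 groups of values tested, where chance gives 25.8. SpdefKO_EC 20 had the smallest depth of its group (10.09 M gene counts, 10085637 in full) and a deposited size factor of 0.674, and SpdefKO_GC 3 a size factor of 1.21. In WT_EC 14, Copb1 (225 CPM), Dnahc5 (25.4 CPM) and Mptx1 (30.7 CPM) were high, the tuft cell median was 0.52 and the dissociation stress median -0.36 on the log2 scale relative to the WT mean of the same fraction. In WT_EC 12, Slc9a3 was at 321 CPM and Foxa3 at 15.3 CPM, and in WT_EC 17 Retnlb was at 0.220 CPM. In WT_GC 13, Spink4 (2506 CPM), Tpsg1 (130.2 CPM) and Trpm5 (11.8 CPM) were high, with medians of 0.0515 for vesicle coats and -0.0884 for tight junction genes. Rab3c was at 1.28 CPM in WT_GC 11 and Mep1a at 36.3 CPM in WT_GC 18.

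In SpdefKO_EC 4, Akr1c21 was at 0.128 CPM and Txndc11 at 30.8 CPM. In SpdefKO_EC 6, Asb11 was at 3.52 CPM, Dzip1l at 0.196 CPM and Fcgbp at 75.5 CPM. In SpdefKO_EC 20, Ndufa7 was at 50.8 CPM and the tuft cell median at -2.16. SpdefKO_GC 3 had Chgb at 102 CPM, and SpdefKO_GC 5 had Oas2 at 10.7 CPM and an immune marker median of 0.96. SpdefKO_GC 19 had Gng2 at 11.02 CPM, Mep1a at 29.6 CPM, Trpm5 at 4.98 CPM and Zg16 at 10756 CPM.

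The genotype difference was unlike in GC and EC for 1231 genes by the edgeR interaction test. Of the named genes 52 passed, 32 with a higher and 20 with a lower change in GC, given here as log2 values. Higher were Abcg1 (4.17), Gng2 (3.95), Neurog3 (3.68), Abcc8 (3.65), Rab3c (3.22), Ret (2.98), Il1b (2.82), Gcg (2.65), Tph1 (2.63), Gpr179 (2.54), Chgb (2.502), Chga (2.29), Sh2d7 (2.15), H2-Eb1 (1.97), Guca2b (1.95), Avil (1.83), Dnahc5 (1.75), Trpm5 (1.74), Muc4 (1.69), Sst (1.44), Guca2a (1.34), Hpgds (1.28), Itgam (1.27), Slc9a3 (1.21), Slc34a2 (1.20), Prss30 (0.93), Tff3 (0.85), Muc2 (0.84), Fcgbp (0.83), Dll1 (0.79), Clca3 (0.70) and Mep1a (0.64). Lower were Kcne2 (-5.68), B3gnt6 (-4.72), Casc4 (-4.01), Creb3l4 (-3.87), Dlk1 (-3.83), Sowaha (-3.57), Pla2g2a (-2.68), Galnt12 (-1.64), Kdelr3 (-0.97), Txndc11 (-0.76), B4galnt2 (-0.75), Slc12a2 (-0.70), Fdps (-0.61), Foxa3 (-0.59), Ern2 (-0.59), Copb1 (-0.52), Sec16a (-0.52), Idi1 (-0.52), Sec24d (-0.44) and Cox8a (-0.36). Calls of Muc2 and H2-Eb1 were lost without the filter on low counts (adjusted p = 0.0811 and 0.104). That of H2-Eb1 was also lost without WT_EC 10 (0.0722), 12 (0.0765) or 17 (0.0602), WT_GC 9 (0.0745), 11 (0.0894), 13 (0.0970) or 18 (0.0715), SpdefKO_EC 8 (0.0644) and SpdefKO_GC 3 (0.0580) or 5 (0.0781). That of Itgam was lost without WT_EC 12 (0.0519) or 17 (0.0755), WT_GC 13 (0.0613) and SpdefKO_GC 19 (0.0508). Against the 1.5-fold bound Muc2, Clca3, Fcgbp, Tff3, Copb1, Sec16a, Ern2, Txndc11, Dll1, Slc12a2, Hpgds, Itgam, Cox8a and H2-Eb1 missed the threshold. Genes above that the rule named only in other comparisons were not run under other settings for the interaction.

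Among the lists 11 passed camera for the interaction, with median log2 values of 2.09 for enteroendocrine markers, 1.39 for tuft cell markers, 1.22 for stromal and endothelial markers, 0.62 for goblet mucus proteins and 0.40 for absorptive markers. Medians were -0.34 for cholesterol synthesis, -0.29 for vesicle coats, -0.24 for O-glycosylation, -0.24 for respiratory chain genes, -0.22 for ER folding and -0.0713 for ribosomal protein genes. With an estimated correlation none of the 11 passed (the lowest adjusted p was 0.0517).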

How the results depend on the processing

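Leaving out adjacent pairs and testing lists with upper-quartile factors or the block were chosen after seeing the data, and the other settings before. Over all settings the gene counts of WT_GC with WT_EC and SpdefKO_GC with SpdefKO_EC stayed within 1.5 times the reported ones except against the 1.5-fold bound, where a larger change is asked for. That bound left 260.0 genes for SpdefKO_GC with WT_GC, 3390.0 for WT_GC with WT_EC, 2892 for SpdefKO_GC with SpdefKO_EC, 133 for SpdefKO_EC with WT_EC and 146 for the interaction. For SpdefKO_EC with WT_EC, limma-voom gave 3031 genes and only the groups compared 1075, and the cause was not tested. For the interaction the block gave 3329, which removes the spread between pairs from the error. With 1 library left out the counts ran over 2033–2487 (SpdefKO_GC with WT_GC), 7444–7855 (WT_GC with WT_EC), 6968–7180.0 (SpdefKO_GC with SpdefKO_EC), 940.0–2253 (SpdefKO_EC with WT_EC) and 857–1511 (interaction). With an adjacent pair left out they ran over 2044–2828, 7052–7483, 6536–6917, 856–2709 and 674–1258 in that order, with fewer libraries in each fit. For SpdefKO_EC with WT_EC, leaving out pairs 11/12, 17/18, 3/4, 9/10 and 5/6 gave 1045, 856, 888, 1004 and 2709. For the interaction, pairs 11/12, 17/18 and 9/10 gave 674, 684 and 780.0.

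Changes near 0 that did not pass in any setting turned sign. Upper-quartile factors gave Agr2 a log2 change of -0.00444 in SpdefKO_GC with WT_GC and Tff3 one of -0.0206 in SpdefKO_EC with WT_EC, and limma-voom gave Muc2 -0.0108 in SpdefKO_GC with WT_GC, and the cause was not tested. With 1 library left out, Agr2 ran over -0.0736 to 0.116 in GC, -0.0741 to 0.252 in EC and -0.223 to 0.0976 in the interaction, Tff3 over -0.0731 to 0.101 in EC and Muc2 over -0.0339 to 0.129 in GC. With pairs left out, Agr2 reached 0.257 and Tff3 0.107 in EC, and the turned values were -0.0341 for Muc2 in GC, -0.0733 and -0.0193 for Agr2 in GC, -0.0743 and -0.0396 for Agr2 in EC, 0.0819 for Agr2 in the interaction, and -0.0724 and -0.0167 for Tff3 in EC. For genes whose calls the report gives, calls that ended with 1 library left out or under a setting other than the pairs are given with the same comparison there. Members of the lists that the text does not name are not covered by this. With an adjacent pair left out, calls of SpdefKO_GC with WT_GC ended for Gbp2 without every pair but 7/8 and 19/20 (adjusted p = 0.0547–0.100) and for Zg16 without 9/10, 11/12, 17/18 or 19/20 (0.0542–0.0909), and Spdef passed without 19/20 (0.0305). In SpdefKO_EC with WT_EC they ended without 6 of the 8 pairs for Iigp1 (0.0507–0.112) and Slc15a2 (0.0512–0.118), without 5 for Ciita (0.0923–0.108), and for Clca3 without 17/18, 19/20 or 3/4 (0.0769, 0.0532 and 0.0560). In the interaction they ended for Muc2 without 13/14, 17/18, 19/20, 7/8 or 9/10 (0.0660–0.0945), for Clca3 without 11/12, 17/18, 19/20 or 3/4 (0.0704, 0.0773, 0.0823 and 0.0504), for Fcgbp without 17/18 or 19/20 (0.0688 and 0.0603), for H2-Eb1 without every pair but 5/6 and 19/20 (0.0644–0.151) and for Itgam without every pair but 13/14, 3/4 and 7/8 (0.0618–0.113). The block changed no call other than those given with the comparisons of GC with EC and the interaction, among the lists and named results it was run on. Upper-quartile factors brought MHC class II presentation past the threshold in WT_GC with WT_EC (adjusted p = 0.0300; 0.486 with an estimated correlation). At this depth and spread, changes of 1.5-fold were recovered in 34.3% of simulated genes for the interaction, so a missed call there does not show equal changes.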

Other observations

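The genes described here were chosen after their values were seen, and no explanation of them was tested. The values of Meg3, Rian, Mirg and Dlk1, from an imprinted cluster on chromosome 12, are given without a test of the cluster as a group. Meg3, a maternally expressed noncoding RNA, was at 110.1 ± 8.46 CPM in WT_GC, 46.6 ± 6.18 CPM in SpdefKO_GC, 0.301 ± 0.114 CPM in WT_EC and 0.129 ± 0.138 CPM in SpdefKO_EC (n = 4 each). It fell by 1.24 ± 0.12 on the log2 scale in SpdefKO_GC (edgeR adjusted p = 3.98e-07). Rian went from 198 ± 8.57 CPM in WT_GC to 64.4 ± 15.5 CPM in SpdefKO_GC (log2 -1.62 ± 0.13, adjusted p = 1.27e-07). Mirg went from 5.53 ± 0.576 to 1.32 ± 0.438 CPM (log2 -2.04 ± 0.24, adjusted p = 6.77e-05) and had 0 CPM in both EC groups. Dlk1, the paternally expressed protein-coding gene beside them, went from 19.1 ± 4.36 to 0.928 ± 0.295 CPM in GC (log2 -4.32 ± 0.27) and was at 0.172 ± 0.170 CPM in WT_EC and 0.113 ± 0.0817 CPM in SpdefKO_EC.

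The heat shock genes Hspa1a and Hspa1b rose in both fractions of libraries labelled SpdefKO, and heat shock genes were not tested as a group. Hspa1a rose by 0.64 ± 0.12 on the log2 scale in GC and by 0.84 ± 0.12 in EC, and Hspa1b by 0.48 ± 0.11 and 0.72 ± 0.11 (edgeR adjusted p = 0.00114, 0.000270, 0.00439 and 0.000391). Both lie within 20 Mb of Spdef, and as near-identical copies they may share reads (compare the odds ratio of 2.37 for genes near Spdef).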
